A study of Homo sapiens with 6 samples.

How the data were processed

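Gene expression was measured in 3 multiple myeloma cell lines, U266, RPMI-8226 and ARP-1, which carried a lentivirus for GFP alone or for CD85j joined to GFP. CD85j is the protein of the gene LILRB1, an inhibitory receptor of leukocytes that binds MHC class I molecules. The virus was made in HEK293T cells and added with 8 µg/mL polybrene, and the transduced cells were sorted by flow cytometry 3 days later. Labelled cRNA was made from 150 ng of total RNA, whose RNA integrity number was above 8 in every sample, and each sample went onto 1 Affymetrix array. There were 6 arrays, with 3 per vector and 2 per cell line. Each line gave 1 GFP array and 1 CD85j array, so the pairs come from the cell line that the labels name. Whether the GFP and CD85j cultures of a line were handled together is not given in the sources used here.

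The deposited values are log2 expression values, which the authors made by RMA (background correction, quantile normalization and probe set summary) in Affymetrix Expression Console 1.1, per the submitters' processing notes. Further settings are not given in the sources used here. The values ran from 3.19 to 14.1, and the medians of the arrays lay between 4.66 and 4.71. They were used as deposited, with no further normalization.

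The arrays held 49386 probe sets, of which 45259 had 1 gene symbol in the platform's gene table, 1327 had several and 2800 had none. Symbols were checked against a RefSeq gene table, which was used for names alone. For each of the 18239 genes with a probe set of its own, the probe set of highest mean over all arrays was kept. Genes whose mean lay above the 40th percentile of all probe sets, a log2 value of 4.36, were tested, which left 11823 genes. Probe sets with several symbols or none entered no test of genes or lists, and the values and counts given for some of them are apart from those tests.

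CD85j was compared with GFP in limma 3.58.1 under R 4.3.3, with the cell line as a block and moderated statistics, and p-values were adjusted by Benjamini-Hochberg over the genes tested. A gene was called at an adjusted p under 0.05. All tests were 2-sided. The 3 pairs left 2 residual degrees of freedom, to which the moderation added 1.9, so the number of arrays limits the precision. Without the U266 pair 1 was left, and the moderation added 5.1. The same held for the cell lines without the array labelled U266 CD85j. The p-values of those fits rest mostly on a spread shared over genes. The p-values measure the spread between these samples. Cell lines were compared in the same way with the vector as a term, and a gene was called at an adjusted p under 0.05 and a fold of at least 2. The comparisons, the gene lists, the rule for named genes and the other settings tried, except where said otherwise, were chosen before the data were examined. Changes within a line rest on 1 array per vector and carry no test.

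A further count took genes at least 1.5-fold apart between CD85j and GFP in the same direction in all 3 lines. It was set against the counts obtained with the vectors exchanged in a line. Changes were also correlated between lines across genes, with LILRB1 left out, and genes are not independent replicates.

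Of 29 fixed gene lists, 27 had at least 5 genes tested. The list of LILR genes other than LILRB1 had 4 and the list of mitochondrially encoded genes had 0, so they were not tested. Lists were tested with limma's camera at a preset correlation between genes of 0.01, with LILRB1 left out, and p-values were adjusted over the lists. Camera was also run with a correlation estimated for each list, and fry was run beside it. For each line, a list's median change was given as its percentile among 10000 random lists of the same size and similar mean expression. The lists of T and NK cell, myeloid, and packaging and epithelial cell markers stood for other cells that a culture or sort could hold.

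Named genes followed a rule. LILRB1 was named in every array. For CD85j against GFP, the 12 genes higher and the 12 lower with the largest mean change among called genes of 1 direction in all lines were to be named. Where fewer were called, places were filled with genes of the same direction in all 3 lines, ranked by their smallest change over the lines. Each list gave up to 4 members with the largest mean change among those of 1 direction in all lines, in the list's own direction where camera called it. Each line gave the 5 highest and 5 lowest genes of its pair. Each line also gave up to 8 genes higher than in both other lines, ranked by the smaller difference, with members of the translocation, B cell, plasma cell and adhesion lists that passed. Genes named outside this rule are said to have been chosen after their values were seen.

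The fits were tested on simulated data, made from the line means and the fitted spread with known changes added to 50 genes at each of 4 fold sizes. For the comparisons of cell lines, the mean over the arrays used took the place of the line means. With 3 pairs, 0% of 50 genes changed 2-fold were called by limma, 78% of those changed 4-fold, 100% of those changed 16-fold and 98% of those changed 64-fold, and 5 of 11623 genes left unchanged were called. Without the U266 pair the same shares were 80%, 100%, 100% and 100%, and 8 of 11623 genes left unchanged were called. Between cell lines with all arrays they were 0%, 34%, 96% and 98%, and without the array labelled U266 CD85j 84%, 100%, 100% and 100%. These shares hold where many genes change together, which eases the adjusted p, so a gene that changes nearly alone can be missed. In the data RAP1A missed with 3 pairs at a mean change of -7.24 (limma adjusted p = 0.835). LILRB1 missed without the U266 pair at 3.12 (limma adjusted p = 0.275). A count of 0 genes called therefore does not show that no gene changed 4-fold or more. Camera called 4 of 4 lists shifted by 0.5 log2 units, together with 3 lists left unshifted with all pairs and 1 without the U266 pair. The simulated genes varied independently, whereas the correlation estimated in the data reached 0.85 in a list. These calls therefore cannot show how often camera errs in the data at the preset correlation.

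The pairs were checked by correlating each array's deviations from the mean of its vector between the GFP and CD85j arrays. The alternatives tried were a fit without the cell line, no filter or a filter at the 60th percentile, all probe sets tested separately, quantile normalization again, centring each array on its median, an intensity trend, a robust fit, array weights, statistics without moderation, no vector term, other fold minimums, an estimated correlation, fry, and leaving out each pair or array. Camera has no robust form, so the lists were not run with it. Genes at least 8-fold higher in both ARP-1 arrays than in the array labelled U266 CD85j were also left out, alone or with the U266 pair, as an alternative chosen after seeing the data. Probe sequences and vector sequences were not used here.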

Results

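The arrays addressed what the inhibitory receptor CD85j changes in myeloma cells when it is put back, in a study of how malignant plasma cells that have lost it escape immune attack. U266, RPMI-8226 and ARP-1 are established human myeloma lines, that is, lines of malignant plasma cells. Line names here are those of the labels, and whether the cells were these lines was not tested. Each line gave 1 array with GFP alone and 1 array with CD85j, so there were 3 arrays per vector and no replicate within a line and vector. Values are log2 RMA expression values, and the array medians lay between 4.66 and 4.71. Changes are log2 CD85j minus GFP, with the SD over pairs and the SE from limma where given. A change or difference with 1 side below 4.36, the filter value, is a lower bound in size.

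The arrays labelled RPMI-8226 resembled each other, and so did those labelled ARP-1, but those labelled U266 did not. Across all probe sets, Pearson's r was 0.993 within the RPMI-8226 pair, 0.988 within the ARP-1 pair and 0.886 within the U266 pair. The array labelled U266 CD85j had r = 0.989 with the RPMI-8226 GFP array and 0.992 with the RPMI-8226 CD85j array. Genes at least 2-fold apart numbered 3448 of 11823 within the U266 pair, 64 within the RPMI-8226 pair and 202 within the ARP-1 pair. Between the array labelled U266 CD85j and the RPMI-8226 CD85j array there were 120. The correlation of deviations within a line was -0.226 for U266, 0.847 for RPMI-8226 and 0.798 for ARP-1, so the cultures of the latter 2 lines separated by line and those of U266 did not. Results with all pairs are therefore given with those without the U266 pair, or pair by pair.

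**Figure D1:**
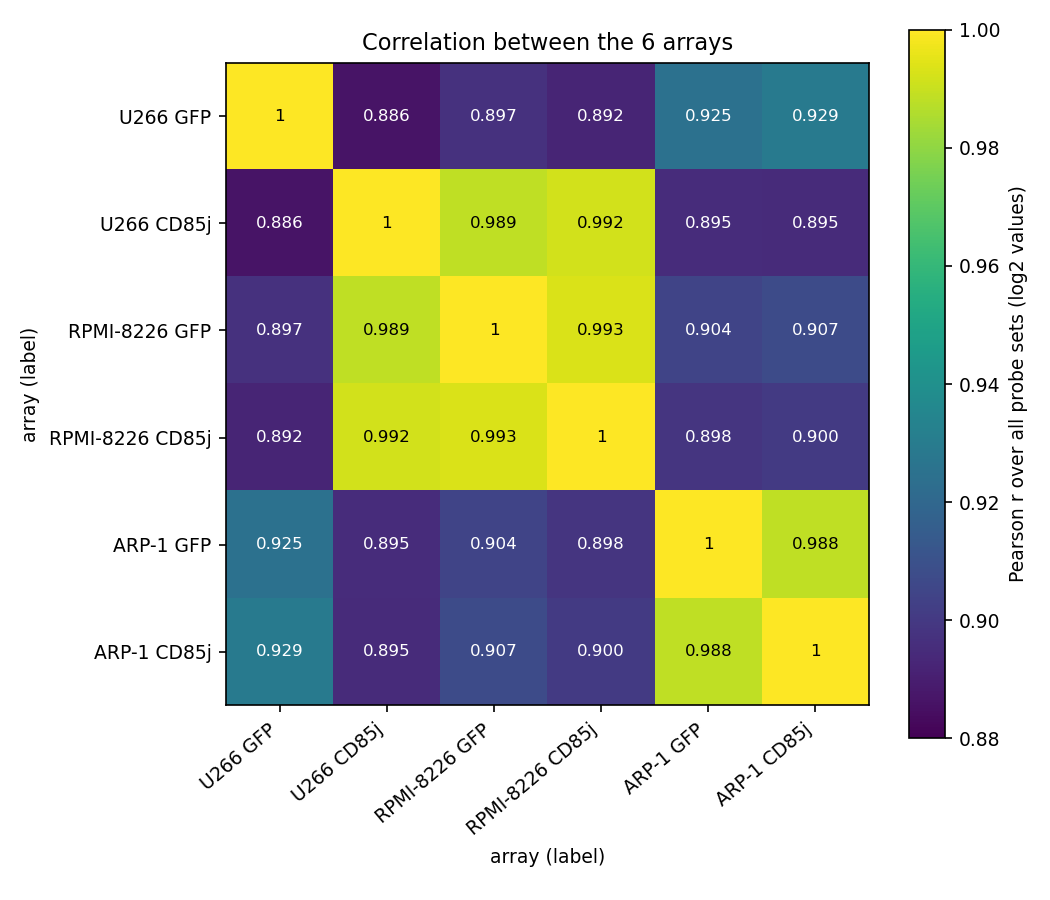
Pearson's r across all probe sets between each 2 of the 6 arrays (log2 values), with arrays on both axes and r as colour and number. The array labelled U266 CD85j lies at 0.989 and 0.992 with the RPMI-8226 arrays and at 0.886 with the U266 GFP array.

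LILRB1, the gene that the CD85j vector carries, was higher in every CD85j array. Its probe set 11749432_a_at read 3.76 in U266 GFP and 5.47 in the array labelled U266 CD85j, 3.45 and 7.21 in the RPMI-8226 pair, and 3.94 and 6.43 in the ARP-1 pair. The mean change was 2.65 ± 1.03 (SD, n = 3 pairs; SE 0.46), higher in 3 of 3 pairs, and missed the threshold over all genes (limma adjusted p = 0.835). Without the U266 pair it was 3.12 ± 0.90 (SD, n = 2 pairs; adjusted p = 0.275). The other 2 probe sets of LILRB1 alone stayed dim with either vector, with means of 3.72 (GFP) and 3.75 (CD85j) for 11732265_at and 3.82 and 3.86 for 11732266_x_at.

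The lowest gene in CD85j cells was RAP1A, which encodes a small GTPase of integrin signalling, by its probe set 11762533_a_at. That probe set read 12.88, 11.93 and 12.89 in the GFP arrays of U266, RPMI-8226 and ARP-1, and 4.80, 5.74 and 5.43 in the CD85j arrays. The mean change was -7.24 ± 0.96 (SD, n = 3 pairs; SE 0.43; adjusted p = 0.835), lower in 3 of 3 pairs. Without the U266 pair it fell by 6.82 and was the single gene past the threshold (SD 0.90, n = 2 pairs; limma adjusted p = 0.00522). It also passed in a fit without the cell line as a block (adjusted p = 0.0298) and with array weights (a change of -6.45, adjusted p = 0.0461). The 3 other RAP1A probe sets changed by -0.66 to 0.26 in the RPMI-8226 and ARP-1 pairs and by 2.35 to 2.93 in the U266 pair, so the fall was seen in 1 of 4 probe sets.

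**Figure D2:**
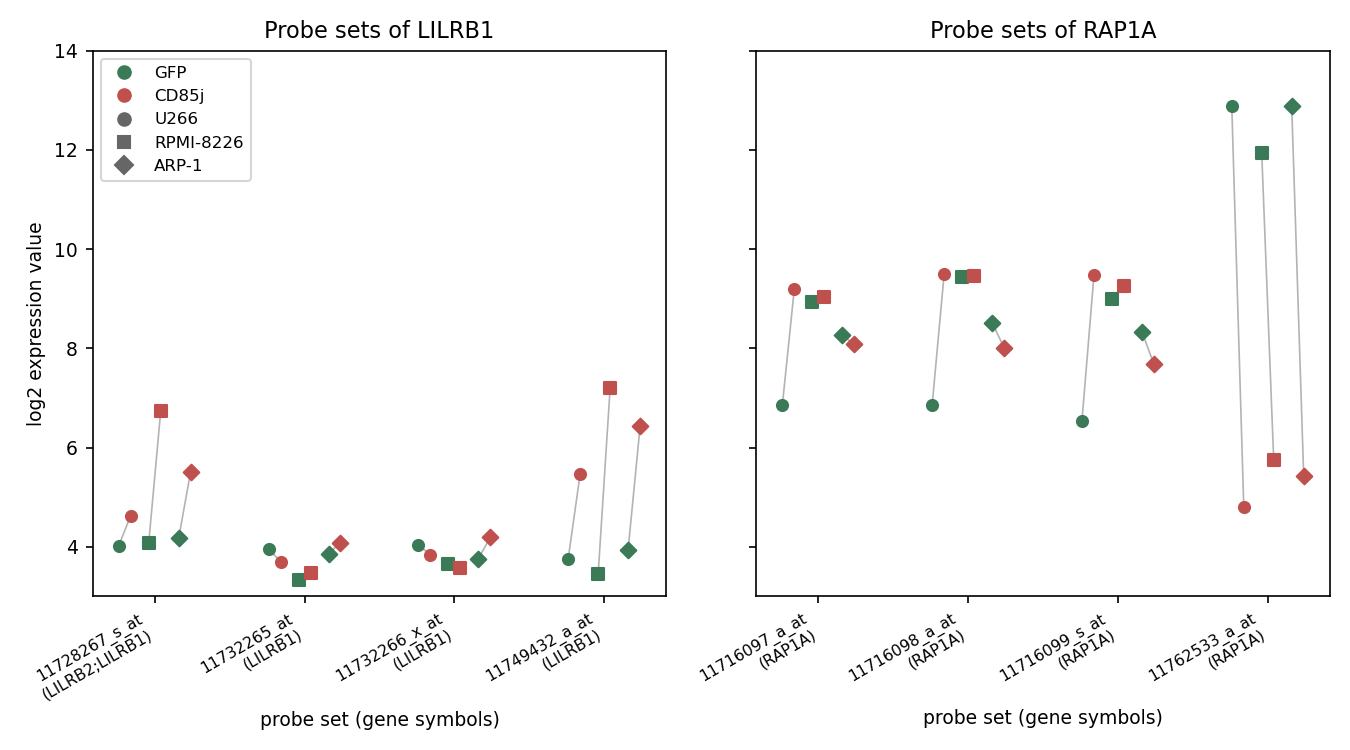
Log2 expression value of each probe set of LILRB1 (left, 1 of them shared with LILRB2) and RAP1A (right) in the 6 arrays, with vector as colour, cell line as shape and lines joining the GFP and CD85j arrays of a cell line. LILRB1 probe set 11749432_a_at lies between 5.47 and 7.21 in the CD85j arrays, and RAP1A probe set 11762533_a_at falls from 11.93 or more in the GFP arrays to 5.74 or less, unlike the other RAP1A probe sets.

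Beside LILRB1, genes higher with CD85j in all 3 lines included HMOX1, heme oxygenase, IFIT2, an interferon-induced antiviral gene, and CMTR2, an enzyme of the mRNA cap. HMOX1 read 5.24 and 7.09, 6.85 and 7.42, and 6.60 and 7.65 in the GFP and CD85j arrays of U266, RPMI-8226 and ARP-1, a mean change of 1.15 ± 0.65 (SD, n = 3 pairs). Without the U266 pair it was 0.81. IFIT2 differed by 1.01 ± 0.41 (0.86 without U266) and CMTR2 by 0.62 ± 0.02 (0.61). The other higher genes were CYP2E1, HACE1, FGR, PREX1, PHLDB2, IER2, SNX22 and UBA7, the last an enzyme of ISG15 conjugation, with mean changes from 0.70 (UBA7) to 1.80 (PREX1), and from 0.52 (IER2) to 0.83 (PREX1) without U266. On the lower side, after RAP1A, stood ST3GAL6, a sialyltransferase, with -2.41 ± 2.52 (-0.95 without U266), and HSPB1, a small heat shock protein, with -2.38 ± 2.83 (-0.75). CHRNA5 differed by -0.73 ± 0.11 (-0.70), and the laminin receptor subunit ITGA6 by -1.32 ± 0.81 (-0.88). PRKACB, TWSG1, SBF2, FKBPL, H2BC11, MGST2 and SLC46A3 had mean changes from -0.87 (SBF2) to -2.60 (MGST2), and from -0.59 (SBF2) to -1.14 (MGST2) without U266. All 24 genes lay on 1 side in 3 of 3 pairs, for which they were picked, and all missed the limma adjusted p, at 0.835. Since the array labelled U266 CD85j resembles the RPMI-8226 arrays, the 3 pairs are not 3 replicates of an effect of CD85j. ST3GAL6 (4.66 in RPMI-8226 GFP, 10.22 in ARP-1 GFP), HSPB1 (6.15 and 11.89), PRKACB and H2BC11 are genes at least 8-fold higher in ARP-1 than in the array labelled U266 CD85j.

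With 3 pairs, limma called 0 genes higher and 0 lower in CD85j, while 39 were higher and 54 lower at an unadjusted p under 0.05, and a fit without moderation also called 0. Leaving out the U266 pair raised the genes at an unadjusted p under 0.05 from 93 to 438 (218 higher, 220 lower), with RAP1A the 1 gene called. Without the RPMI-8226 pair limma called 0 (69 at an unadjusted p under 0.05), and without the ARP-1 pair 0 (29).

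At least 1.5-fold in the same direction in all 3 lines, LILRB1 and CMTR2 were higher and RAP1A, ST3GAL6, HSPB1, CHRNA5, PRKACB and TWSG1 were lower, 8 genes in all. With the vectors exchanged in a line, the total was 4 (RPMI-8226), 15 (ARP-1) or 5 (both of these), so the count does not stand above the exchanged ones. In RPMI-8226 and ARP-1 alone, 9 genes were higher and 9 lower, 18 in all, against 24 with the vectors exchanged in ARP-1. Without genes at least 8-fold higher in ARP-1, 3 of the lower genes were left, an alternative chosen after seeing the data.

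Among gene lists, those of antigen presentation lay higher in CD85j, and histone genes lower, both with all pairs and without the U266 pair. The MHC class II list, which presents peptides to CD4 T cells, lay higher with 3 pairs (camera adjusted p = 5.08e-05, 14 genes) and without U266 (0.00242), with adjusted p = 0.631 and 0.752 with an estimated correlation. The MHC class I list, the ligands of CD85j and the machinery that loads them, lay higher with 3 pairs (adjusted p = 0.00454, 20 genes) and without U266 (0.00629), with adjusted p = 0.631 and 0.802 with an estimated correlation. Of the MHC class II genes 7 were higher in all 3 lines and 0 lower, and of the MHC class I genes 8 were higher and 1 lower. In the U266 pair 13 of 14 class II genes and 12 of 20 class I genes were higher, so few class II genes could be lower in all 3 lines. Here and below, such counts stand without the share over all genes and are no test of agreement between lines. HLA-DRA differed by 6.72, 0.05 and 2.92 in the U266, RPMI-8226 and ARP-1 pairs, and HLA-DPA1 by 5.70, 0.02 and 2.05. HLA-DPB1 differed by 2.40 ± 3.03 (SD, n = 3 pairs; 0.68 without U266) and HLA-DRB1 by 2.20 ± 3.39 (0.25). Of the MHC class I genes, HLA-F differed by 3.27, 0.06 and 1.63, NLRC5, the transactivator of MHC class I genes, by 1.80, 0.29 and 1.64, PSMB9 by 0.99 ± 1.04 (0.43 without U266) and PSMB8 by 0.68 ± 0.66 (0.32). In RPMI-8226 the list medians were 0.04 (class I) and 0.003 (class II), so the values rest on U266 and ARP-1, and without U266 on ARP-1.

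Replication-dependent histone genes, which are transcribed in S phase, lay lower with 3 pairs (camera adjusted p = 0.00939, 20 genes) and without U266 (0.000482), with adjusted p = 0.631 and 0.752 with an estimated correlation. Of them 6 were lower and 2 higher in all 3 lines. In RPMI-8226 the list median was -0.02 (percentile 33.6 of random lists), with 10 of 20 genes higher, so the value without U266 rests on ARP-1. The named genes are among the 6. H2AC11 differed by -3.48, -0.37 and -1.68 in the U266, RPMI-8226 and ARP-1 pairs, H2BC4 by -2.75, -0.24 and -1.58, H1-2 by -3.45, -0.17 and -0.07, and H2BC11 by -2.36, -0.56 and -0.75. Heat shock genes, chaperones of misfolded proteins, lay lower without U266 (adjusted p = 0.000482, 19 genes), with adjusted p = 0.752 with an estimated correlation. With 3 pairs the list missed the threshold (0.0513). Its median was 0.10 in the U266 pair, where 12 of 19 genes were higher, -0.05 in RPMI-8226 and -0.27 in ARP-1, so the value rests mostly on ARP-1. The named genes are among the 6 lower in all 3 lines. Beside HSPB1, DNAJB4 and BAG3 had mean changes of -0.87 and -0.76 (-0.22 and -0.27 without U266), and HSPA1B differed by -1.19, -0.42 and -0.45.

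The other lists called with 3 pairs did not pass without the U266 pair. NF-kB targets lay higher (camera adjusted p = 9.59e-06, 0.491 without U266), with 6 of 24 genes higher in all 3 lines and 0 lower. In the U266 pair 23 of the 24 were higher, which nearly fixed the count of 0. TNFAIP3 differed by 5.07, 0.03 and 0.47 in the U266, RPMI-8226 and ARP-1 pairs, CCL3 by 4.37, 0.11 and 1.06, and NFKBIA and NFKBIE had mean changes of 1.27 and 0.90 (0.16 and 0.31 without U266). Genes of the mature B cell program lay higher (0.00249, 0.268 without U266; 8 of 21 genes higher in all 3 lines, 0 lower), and MS4A1, which encodes CD20, EBF1, CD40 and CD22 had mean changes of 2.62, 1.73, 1.55 and 1.36, and of 0.17, 0.20, 0.20 and 0.25 without U266. Chemokines and cytokines lay higher (0.00249, 0.444 without U266; 5 of 17 genes higher in all 3 lines, 0 lower), with CCL20 at 2.17, CCL5 at 0.76 and IL16 at 0.47, and at 0.22, 0.51 and 0.14 without U266. Cholesterol biosynthesis lay higher (camera adjusted p = 9.59e-06, 0.0734 without U266), with 13 of 24 genes higher in all 3 lines and 0 lower. Among them were ACAT2 (0.88, and 0.06 without U266), MVK (0.66 and 0.11), SQLE, which differed by 1.57, 0.17 and 0.40, and FADS2, by 3.75, 0.12 and 0.03. The median of this list was 0.84, 0.12 and 0.14 in the U266, RPMI-8226 and ARP-1 pairs. These medians lay at percentiles 100, 99.98 and 98.14 of random lists, so the list was not high in the U266 pair alone. Of the 24 genes 20 were higher in RPMI-8226 and 16 in ARP-1. Type I interferon response genes lay higher (0.00426, 0.268 without U266; 5 of 33 genes higher in all 3 lines, 2 lower), with SAMD9L at 0.59, PLSCR1 at 0.49 and IFI6 at 0.42 beside IFIT2, and at 0.31, 0.48 and 0.08 without U266. Without U266 the direction of this list turned to lower, with a median change of -0.05. Inhibitory checkpoint ligands and receptors lay higher (0.0327, 0.733 without U266; 5 of 15 genes higher in all 3 lines, 2 lower), with CD200 at 1.05, CD274, which encodes PD-L1, at 0.64, CEACAM1 at 0.36 and TNFRSF14 at 0.25, and at 0.41, 0.13, 0.40 and 0.35 without U266, where the list's median change was -0.007. For each of these 6 lists the call ended at adjusted p = 0.631 with an estimated correlation.

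On the lower side, the plasma cell identity list (camera adjusted p = 0.0179, 0.491 without U266) had 4 of 23 genes lower in all 3 lines and 1 higher. SDC1, which encodes CD138, differed by -6.71, -2.01 and -0.49 in the U266, RPMI-8226 and ARP-1 pairs, PRDM1, a plasma cell transcription factor, by -6.29, -1.61 and -0.16, and TNFRSF17, which encodes BCMA, and CAV1 had mean changes of -1.51 and -1.33 (-0.33 and -0.60 without U266). The camera adjusted p of the list was 0.631 with an estimated correlation. SDC1, PRDM1 and CAV1 are among the 85 genes at least 32-fold higher in ARP-1 than in the array labelled U266 CD85j. The unfolded protein response (0.00454, 0.268 without U266) and amino acid response (0.00249, 0.217 without U266) lists had adjusted p = 0.662 with an estimated correlation. In each, 2 genes were lower in all 3 lines and 0 higher, SEL1L (-3.57, -0.09 and -0.23 in the 3 pairs) and EDEM1 (mean -0.29, and -0.13 without U266) in the former, DDIT4 (-0.26 and -0.12) and WARS1 (-0.21 and -0.11) in the latter. Without U266 the direction of both lists turned to higher, with median changes of 0.05 and 0.06. SDC1 read 10.79 in U266 GFP and 4.08 in the array labelled U266 CD85j, and MS4A1 4.20 and 11.71, and in the RPMI-8226 CD85j array they read 3.66 and 11.42. In all, camera called 8 lists higher and 4 lower with 3 pairs, and 2 higher and 2 lower without U266, of which 3 were among the 12. With an estimated correlation 0 lists were called (smallest adjusted p = 0.631), and fry, which does not compare a list with other genes, called 0 (0.659). In each list, limma called 0 members over all genes and 0 adjusted over the list alone, against 93 of 11823 genes at an unadjusted p under 0.05.

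**Figure D3:**
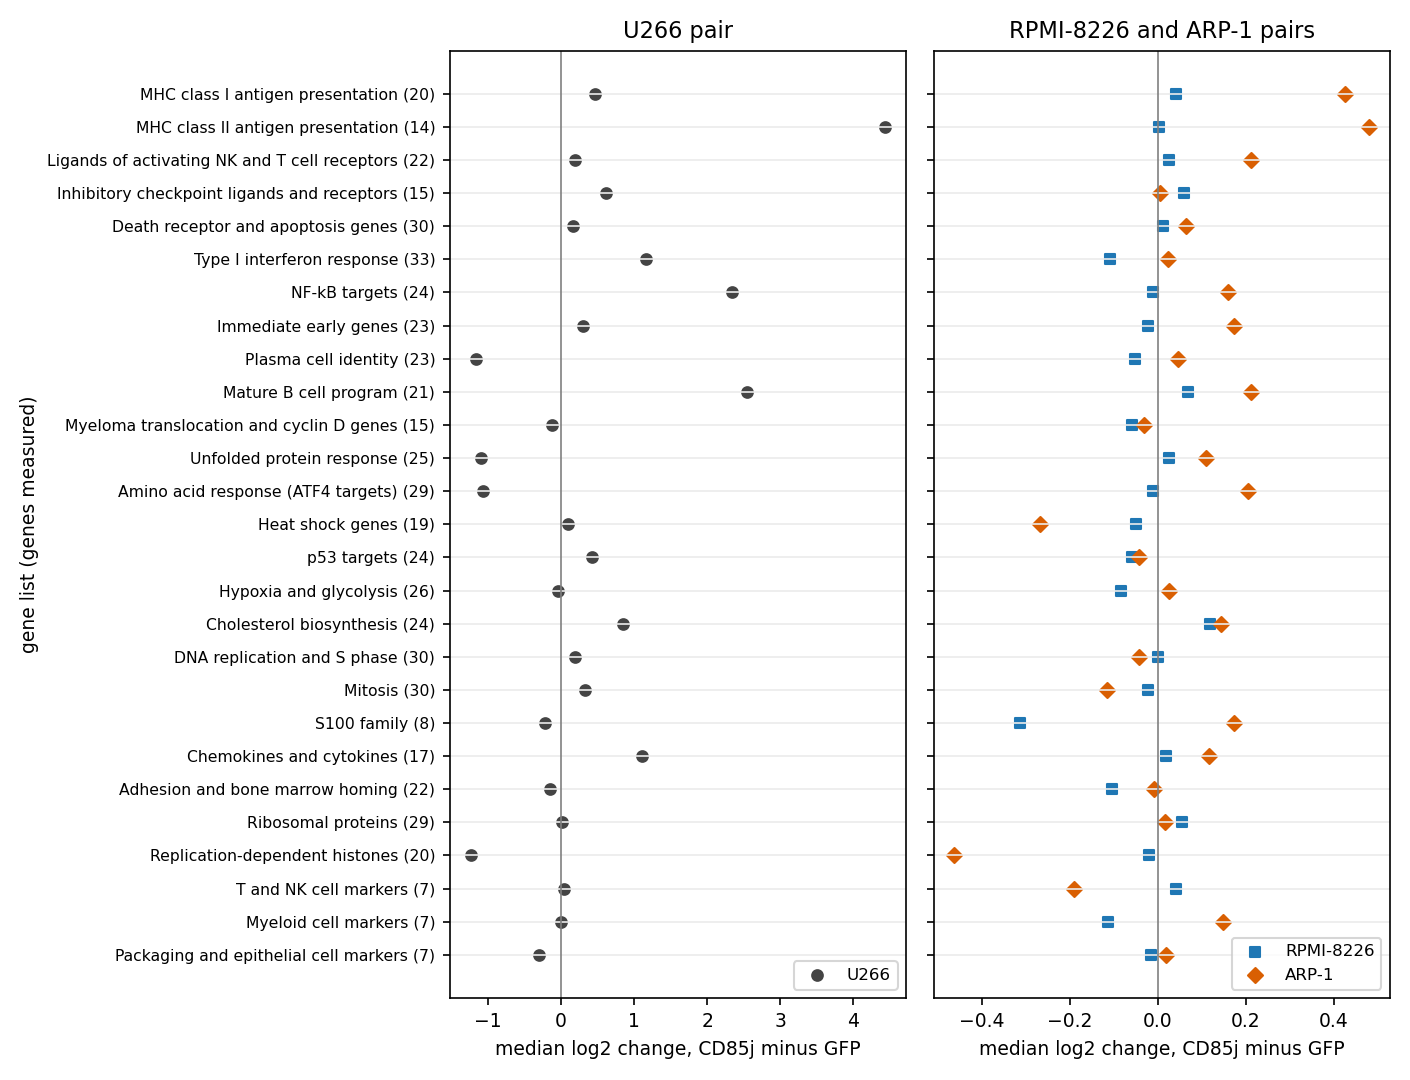
Median log2 change (CD85j minus GFP, horizontal axis) of each of the 27 gene lists tested, with the genes measured in parentheses, in the U266 pair (left) and in the RPMI-8226 and ARP-1 pairs (right, on a narrower scale). The MHC lists lie at 0.43 and 0.48 in the ARP-1 pair and the histones at -0.46, whereas MHC class II lies at 4.44 in the U266 pair.

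Markers of other cells were not called as lists. Those of T and NK cell markers (camera adjusted p = 0.600), myeloid markers (0.946), and packaging and epithelial markers (0.881) missed the threshold with 3 pairs. NCAM1, GNLY, CD4 and CD7 were the named T and NK genes, with mean changes between -0.64 and 0.39, and between -0.29 and 0.56 without U266. VCAN (1.39, and 0.42 without U266) and CLEC7A (-0.65) were the named myeloid genes, and CAV1 the packaging and epithelial gene. The myeloid list was tested as lower although its median change was 0.02 and its mean change 0.13. Without U266, CLEC7A passed adjusted over the list alone (mean change -0.73 ± 0.22, SD, n = 2 pairs), the 1 gene of any list to do so, and it missed the threshold over all genes (limma adjusted p = 1.00). CLEC7A is among the 85 genes at least 32-fold higher in ARP-1 than in the array labelled U266 CD85j, and it differed by -0.89 in the RPMI-8226 pair and -0.57 in the ARP-1 pair.

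Within ARP-1, where each vector had 1 array, 593 genes were at least 1.5-fold higher with CD85j and 479 lower. The higher ones included 7 of 20 MHC class I and 4 of 14 MHC class II genes. HLA-DRA, the alpha chain of HLA-DR, read 6.37 with GFP and 9.28 with CD85j, HLA-B 10.60 and 12.41, and TAP1 and PSMB9, of peptide transport and the immunoproteasome, were higher by 0.80 and 0.78. In the same pair HLA-DQA1 differed by -0.05, HLA-G by -0.26 and PDIA3 by -0.46. HLA-B, TAP1, HLA-G and PDIA3 were chosen after their values were seen. The median change was 0.43 for MHC class I and 0.48 for MHC class II, each at percentile 100 of random lists, while that of the type I interferon list was 0.02 (percentile 44.2). The histone median was -0.46 and the heat shock median -0.27, each at percentile 0. Among 42 genes at least 32-fold higher in the RPMI-8226 arrays and the array labelled U266 CD85j than in U266 GFP and ARP-1 GFP, 29 were higher in ARP-1 CD85j, with a median change of 0.22. PROK2, HLA-DRA, SPINK2, RUNX3, a transcription factor of lymphocytes, and ANXA1 were the highest genes, by 2.58 (ANXA1) to 3.19 (PROK2). ZAP70, CTHRC1, CRYBB1, SFRP2 and GRAMD2B were the lowest, by -2.15 (ZAP70) to -1.79 (GRAMD2B).

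**Figure D4:**
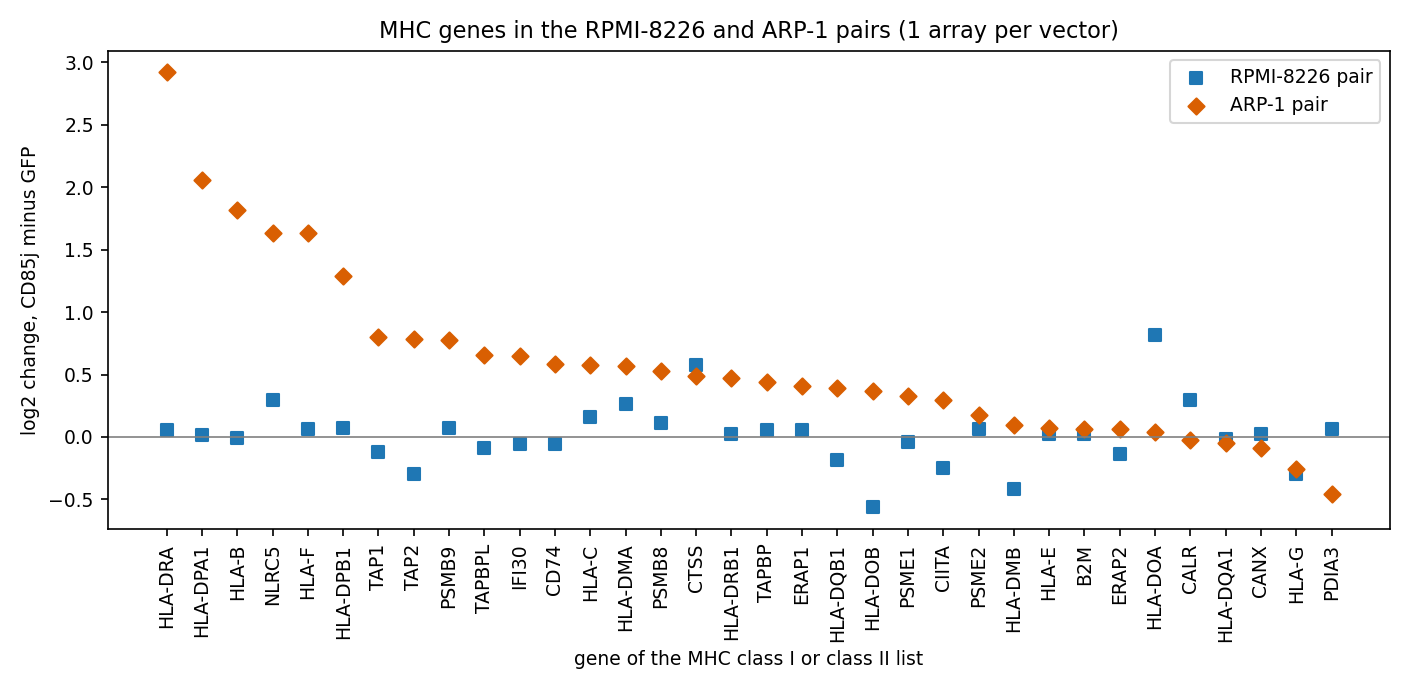
Log2 change (CD85j minus GFP, vertical axis) of each tested gene of the MHC class I and class II lists in the RPMI-8226 and ARP-1 pairs, 1 array per vector and line. HLA-DRA lies at 2.92 and HLA-B at 1.82 in ARP-1, and they lie at 0.05 and -0.01 in RPMI-8226.

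Within RPMI-8226, 172 genes were at least 1.5-fold higher with CD85j and 247 lower, and the lower ones included some genes of antibody-secreting cells. The plasma cell identity list as a whole had a median change of -0.05 (percentile 7.61 of random lists). Of its 23 genes 9 were higher, and 4 were at least 1.5-fold lower. IGKC, an immunoglobulin light chain, differed by -2.75 in its probe set 11763663_x_at, IGHA1, the heavy chain of IgA, by -2.55, and JCHAIN, which joins IgA and IgM units, by -2.03. CHPT1 differed by -2.75, CTSB by -2.09 and EMC10 by -2.05. All of them were abundant in ARP-1, where IGKC read 12.67 with GFP and IGHA1 12.51. Of 85 genes at least 32-fold higher in both ARP-1 arrays than in the array labelled U266 CD85j, 81 were higher in RPMI-8226 GFP than in RPMI-8226 CD85j, with a median change of -0.86. The highest genes, PXK, SLX4IP, GATA2, CYP3A7 and MYL5, differed by 1.35 (PXK) to 1.02 (MYL5). Without the genes at least 8-fold higher in ARP-1, 159 genes were lower.

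Within the U266 labels, 2669 genes were at least 1.5-fold higher and 3023 lower in the array labelled CD85j. Among the highest were HLA-DQA1, LINC00158, CCL22, a chemokine, MS4A1 and BCHE, each by at least 7.45, and among the lowest CLEC2B, UCHL1, FGFR3, JCHAIN and CTHRC1, each by -7.72 or further. LINC00158, MS4A1 and BCHE read 4.20 or less in U266 GFP, and CLEC2B, UCHL1, FGFR3 and CTHRC1 4.33 or less in the array labelled U266 CD85j, below the filter value, so their order carries no weight. MS4A1 read 11.71 in the array labelled U266 CD85j and 11.29 and 11.42 in the RPMI-8226 GFP and CD85j arrays, and HLA-DQA1 read 12.19, 12.37 and 12.36. Across 11822 genes the changes had r = 0.205 (Spearman's rho 0.154) between U266 and RPMI-8226, -0.0062 (-0.0634) between U266 and ARP-1, and 0.0151 (-0.0503) between RPMI-8226 and ARP-1. Without the genes at least 8-fold higher in ARP-1 than in the array labelled U266 CD85j, a choice made after the results were seen, r between U266 and RPMI-8226 was 0.132. These values are across genes, which are not independent replicates, so no p is given.

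The cell lines themselves were compared to set the effect of the vector beside the differences between lines. ARP-1 stood out by MAF and by a probe set of IGKC. IGKC, by probe set 11763663_x_at, was at least 7.39 log2 units higher in ARP-1 than in either other line (SE 0.83, n = 2 arrays per line, limma adjusted p = 0.0480), and MAF, a transcription factor that translocations activate in myeloma, by at least 6.61 (SE 0.50, adjusted p = 0.0278). Another probe set, 11763550_x_at, which has the symbols IGKC and IGK, read between 11.53 and 13.74 in all 6 arrays. IGHM, the heavy chain of IgM, read 9.47 and 9.59 in the RPMI-8226 GFP and CD85j arrays and 4.78 and 4.84 in the ARP-1 arrays (probe set 11759815_a_at). The same IGHM probe set read 4.38 in U266 GFP and 9.27 in the array labelled U266 CD85j. Probe set 11763550_x_at and IGHM were chosen after their values were seen. PAGE5, GPRC5D, a myeloma surface antigen, PAPSS2, CAV2, CLEC7A and LAMP5 followed, among 158 genes higher in ARP-1 than in both other lines. With all 6 arrays, 45 genes were higher and 170 lower in U266 than in ARP-1, and 76 higher and 181 lower in RPMI-8226 than in ARP-1. Between U266 and RPMI-8226 limma called 0 genes higher and 0 lower, with 189 at an unadjusted p under 0.05 and a smallest adjusted p of 0.240. With any 1 of the RPMI-8226 or ARP-1 arrays left out, limma called 0 genes in both comparisons with ARP-1, with 713 to 1391 genes at an unadjusted p under 0.05.

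Without the array labelled U266 CD85j, the U266 GFP array was marked by FGFR3, a receptor kinase that translocations activate in myeloma together with NSD2, and by CLEC2B and UCHL1, a ubiquitin hydrolase of neurons. That leaves 1 array for U266, which is assumed to vary like the other arrays. FGFR3 read 12.49 in U266 GFP and between 3.76 and 4.32 in the other 5 arrays, a difference of at least 8.16 (SE 0.22, limma adjusted p = 7.51e-05). HRC, BEX3, QPCT, SELENOP and CPVL followed among 646 genes. The arrays labelled RPMI-8226 were marked by HLA-DQA1, LINC00158, MS4A1, the chemokine receptor CCR7, CCL22, BASP1, GPX1 and PLEK, among 832 genes. The 622 genes of ARP-1 included ITGB7, an integrin chain that MAF is known to induce, which read 12.38 with GFP and 12.35 with CD85j. The counts without that array were 1704 higher and 1581 lower in U266 than in RPMI-8226, 1226 and 1355 in U266 than in ARP-1, and 1351 and 1531 in RPMI-8226 than in ARP-1.

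By list and without that array, 14 of 21 mature B cell genes were higher in RPMI-8226 than in ARP-1 and 2 lower, among them CD40, MS4A1 and BLNK, which was higher by 5.31. CD40 read 10.61 and 10.96 in the RPMI-8226 GFP and CD85j arrays and MS4A1 11.29 and 11.42, while both read 4.05 or less in ARP-1, below the filter value of 4.36, so their differences are lower bounds. Of 23 plasma cell genes 18 were higher in ARP-1 and 2 in RPMI-8226, with SDC1 at 11.42 in ARP-1 GFP and 5.67 in RPMI-8226 GFP, and CD38 at 8.19 and 5.61. Of 22 adhesion genes 8 were higher in each of them, CCR7 and ALCAM in RPMI-8226 and ITGB7 and ITGB1 in ARP-1. Of 15 translocation and cyclin D genes 7 were higher in ARP-1, including MAF, CCR1 and NUAK1, and 1 in RPMI-8226, MAP3K14. CCND2 read 5.03 in U266 GFP and between 11.91 and 12.12 in the other arrays. CCND1, the cyclin that a rearrangement drives in U266, was dim in both arrays with that label, between 3.50 and 4.54 over its 4 probe sets, and it was chosen after its values were seen. MAF, which a rearrangement activates in RPMI-8226, read 5.67 with GFP and 3.69 with CD85j in the arrays with that label. These values differ from what is known of U266 and RPMI-8226, and whether those labels name the right cells was not tested. Of the lists chosen after their values were seen, 17 of 24 NF-kB targets and 11 of 14 MHC class II genes were higher in RPMI-8226 than in ARP-1, and 0 of either in ARP-1. With all 6 arrays limma called fewer of these genes between RPMI-8226 and ARP-1 (2936 of all genes had an unadjusted p under 0.05): 1 B cell gene higher and 0 lower, 0 plasma cell genes higher and 2 lower, 1 adhesion gene higher and 2 lower, 0 translocation and cyclin D genes higher and 4 lower, and 0 NF-kB and MHC class II genes.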

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

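The tests of the explanations and the counts over other splits of the arrays in this part were chosen after the results were seen.

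The array labelled U266 CD85j lay apart from the U266 GFP array, with 3448 genes 2-fold apart, and near the RPMI-8226 CD85j array, with 120. A wrong label or tube may account for this, since 120 lies between the 64 genes within the RPMI-8226 pair and the 202 within the ARP-1 pair, and far below the smallest count between different lines, 2589. A mixture of U266 and RPMI-8226 cells is argued against: 275 genes at least 8-fold higher in U266 GFP than in the RPMI-8226 arrays kept a median of -0.346% of the U266 GFP signal (quartiles -1.33% and 0.300%). An effect of CD85j in U266 cells cannot be told apart from a wrong label by a further U266 pair, because there is none, and the changes of U266 and ARP-1 had r = -0.0062 across genes. Between U266 GFP and the RPMI-8226 CD85j array, 3353 of 11823 genes were 2-fold apart. An effect of CD85j in U266 cells alone would have to bring that count to 120. In the RPMI-8226 and ARP-1 pairs the same vectors came with 64 and 202 genes 2-fold apart. The same array held LILRB1 at 5.47, above the 3.94 or less of the GFP arrays.

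RAP1A probe set 11762533_a_at read 11.9 or more in every GFP array and 5.74 or less in every CD85j array, and it was the 1 probe set of 49386 at least 4 log2 units apart in the same direction in every line. A fall of the RAP1A transcript is argued against, since the lowest change of the other 3 probe sets in the RPMI-8226 and ARP-1 pairs was -0.66. The normalization of the arrays is argued against, since the mean change was -7.23 or larger in size with the arrays normalized another way. Control vector RNA that binds the probes is a candidate explanation, for which the lowest GFP value was 11.93, but it cannot be told apart from a change of 1 RAP1A transcript form without the probe and vector sequences, which were not used here.

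Of 23 plasma cell genes 4 were at least 1.5-fold lower in the RPMI-8226 CD85j array than in the RPMI-8226 GFP array and 0 higher, with a list median of only -0.05, and 9 of the 10 lowest genes were among the 85 at least 32-fold higher in ARP-1. ARP-1 RNA or cells in the RPMI-8226 GFP sample may account for this: 81 of the 85, picked without the RPMI-8226 arrays, were higher there, by a median of 1.14% of the ARP-1 signal (quartiles 0.606% and 1.98%). U266 RNA or cells as the whole source are argued against: of 34 genes at least 16-fold higher in U266 GFP 23 were higher there, but by a median of 0.029% of its signal (quartiles -0.0271% and 0.479%), while all 13 genes at least 32-fold higher in ARP-1 than in either U266 array were higher. An effect of CD85j shared with ARP-1 is argued against for these genes, since the median change of the 85 genes in the ARP-1 pair was -0.016 (quartiles -0.18 and 0.17). The pick needed both ARP-1 arrays to be high, which leaves out genes that fell far there. An effect of CD85j in RPMI-8226 alone stays open and was not tested. The 85 genes were picked as dim in the array labelled U266 CD85j, which resembles the RPMI-8226 arrays. That array also carries CD85j, so the count of 81 cannot tell such an effect from ARP-1 RNA or cells.

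The U266 GFP array, with FGFR3 at 12.49 and CCND1 at 4.54 or less, and the RPMI-8226 arrays, with MAF and SDC1 at 5.67 or less and the brightest MS4A1 probe set at 11.29 or more, differ from what is known of these lines, and whether their labels name the right cells was not tested, so each statement on a line holds for its label.

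The 6 arrays make 10 splits into 3 and 3, so the share of splits cannot be under 0.05. For the genes called, the real split gave 0, so all 10 splits had to give as many and the comparison decides nothing. The highest other was 4578, and it was 0 among the splits that part all 3 pairs. The splits with 4578 part the U266 pair alone. With the cell line as a block, they compare U266 GFP with the array labelled U266 CD85j. Their count thus restates the difference within that pair, whichever side the other arrays are on. For the lists called, the real split gave 12, 1 of 10 splits gave as many, itself, and the highest other was 11. Among the 4 splits that part all 3 pairs, the real split had 93 genes at an unadjusted p under 0.05 and the highest other 130, and the highest other count of lists was 11. The other splits part 1 pair.

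Some list medians went in opposite directions in different lines, and the differences were not tested. The type I interferon list had a median change of 1.17 in the U266 pair (percentile 100 of random lists) and -0.11 in the RPMI-8226 pair (percentile 2.21). The unfolded protein response list had -1.10 in the U266 pair (percentile 0) and 0.11 in the ARP-1 pair (percentile 97.5). The amino acid response list had -1.06 in the U266 pair (percentile 0) and 0.20 in the ARP-1 pair (percentile 99.9).

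Outside the genes tested, a probe set shared by LILRB2 and LILRB1 was higher in every CD85j array, by 0.61, 2.66 and 1.34, a mean of 1.53 ± 1.04 (SD, n = 3 pairs). It was 1 of 2 probe sets without a single symbol, of 2181, at least 1.5-fold higher in every CD85j array, against 0 lower and totals of 2 to 5 with the vectors exchanged in a line. The other, 11737030_at, has no symbol and was higher by 1.65, 0.59 and 0.75.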

How the results depend on the processing

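The alternatives that leave out genes far higher in ARP-1 were chosen after the results were seen, and the others were planned. Of 246 values of comparisons under an alternative, 152 stayed within 1.5 times the count or within the spread of the value, and 94 moved. Of 1682 values of named genes, each of the change the gene was named for, 1678 were counted as the same, 4 passed the threshold, all of RAP1A, and 0 reversed. Over the lines, the same means the same direction and side of the threshold. Within 1 line, where there is no test, it means the same direction and a move smaller than the gene's SD over the pairs. That SD was 5.18 for CLEC2B, so the rule is loose. Genes named over the lines had 1 direction in all of them, so leaving out a pair could not reverse them. A fit without the cell line, an intensity trend or a robust fit leaves the change itself as it was. Means over the lines of genes named within 1 line were not counted, and 5 of them turned without U266: SPINK2 from -0.62 to 1.56, PXK from -0.07 to 0.81, BCHE from 2.03 to -0.68, HLA-DQA1 from 2.49 to -0.03 and CLEC2B from -2.97 to 0.02. No filter, an intensity trend, a robust fit, statistics without moderation and the adjusted p without a fold moved no comparison. The cause of a move was not tested unless the alternative itself shows it. Signal over background limits LILRB1, which lay at 3.94 or less in every GFP array.

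With fewer genes, at the 60th percentile filter, 1 gene was higher the same way in every line, the RPMI-8226 pair had 78 higher and 161 lower, the ARP-1 pair 308 lower, U266 minus ARP-1 19 higher and 30 lower, and RPMI-8226 minus ARP-1 26 and 36. With all probe sets, and so more tests, 12 were higher and 17 lower in every line, U266 had 8041 and 6432, RPMI-8226 688 and 555, ARP-1 1265 and 2342, U266 minus ARP-1 70 and 318, and RPMI-8226 minus ARP-1 125 and 365. Quantile normalization again left 1 gene higher in every line, and centring the arrays on the median 3 lower.

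Without the replicate block, that is the cell line, 1 gene was lower in CD85j, RAP1A. Array weights called 1 gene lower, 1 list higher and 0 lower by camera, 23 genes higher and 52 lower in U266 than ARP-1, and 1320 and 1484 in RPMI-8226 than ARP-1. Without a vector term 1 gene was lower in U266 than RPMI-8226, 140 higher and 333 lower in U266 than ARP-1, and 242 and 399 in RPMI-8226 than ARP-1. An estimated correlation called 0 lists higher and 0 lower, and so did fry (0 and 0). At 1.3-fold, 32 genes were higher and 46 lower in every line, 698 and 711 in RPMI-8226, and 1516 and 1234 in ARP-1. At 2-fold they were 1 and 1, 1654 and 1794 in U266, 9 and 55 in RPMI-8226, and 103 and 99 in ARP-1.

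Leaving out a pair in turn gave 0 to 1 gene lower in CD85j, 2 to 8 lists higher and 2 to 5 lower, and 9 to 144 genes higher and 9 to 138 lower the same way in the lines left. The counts of genes the same way were 9 and 9 without U266, 144 and 138 without RPMI-8226, and 61 and 135 without ARP-1, where fewer lines have to match. Leaving out an array in turn gave 0 to 1704 genes higher and 0 to 1581 lower in U266 than RPMI-8226, 0 to 1378 and 0 to 1652 in U266 than ARP-1, and 0 to 1351 and 0 to 1531 in RPMI-8226 than ARP-1. The highest came without a U266 array and the counts of 0 against ARP-1 without an RPMI-8226 or ARP-1 array (limma, 713 to 1391 at an unadjusted p under 0.05), and the line left with 1 array is assumed to vary like the others.

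Without the 330 genes at least 8-fold higher in ARP-1, 11493 genes were left, 3 were lower in every line, and 159 were lower in RPMI-8226. Without these and the U266 pair, 1 gene was lower in CD85j, 2 lists were higher and 2 lower, and 9 genes were higher in both lines left. Camera has no robust form and was not run with it.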

Other observations

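The percentages of RPMI-8226 signal in the ARP-1 pair in this part were computed after the results were seen.

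None of the following lists passed with 3 pairs, and values in parentheses after a gene are its mean changes with 3 pairs and without U266. DNA replication genes (camera adjusted p = 0.122, 30 genes) had MCM10 (0.44, 0.20), FEN1 (0.17, 0.09) and CDT1 (0.16, 0.13) higher in all 3 lines. Mitosis genes (0.293) included MKI67 (0.14, 0.10) and BUB1B (0.12, 0.17), with CCNB2 (-0.15, -0.12) and UBE2C (-0.06, -0.08). Ribosomal proteins (0.300) had RPS9 (0.13, 0.06), RPL27 (0.10, 0.05) and RPL11 (0.07, 0.01) higher in all 3 lines and RPS13 (-0.05, -0.05) lower. For p53 targets (0.727) SESN1 (-1.36, -0.11) and DDB2 (-0.51, -0.24) were lower in all 3 lines and TNFRSF10B (0.75, 0.10) and XPC (0.53, 0.20) higher. For hypoxia and glycolysis genes (0.583) ADM (-2.60, -0.36) and NDRG1 (-1.26, -0.46) were lower in all 3 lines and EGLN3 (1.51, 0.11) and ALDOC (1.17, 0.10) higher. Immediate early genes (0.137) had DUSP2 (1.39, 0.29), DUSP4 (1.07, 0.06), IER5 (1.00, 0.05) and IER2 higher in all 3 lines, and IER2 differed by 3.13, 0.53 and 0.51 in U266, RPMI-8226 and ARP-1.

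Further lists that did not pass concern surface and signalling genes. Ligands of activating NK and T cell receptors (camera adjusted p = 0.293, 22 genes) had CD86 (2.36, 0.40), CD48 (1.78, 0.46), CD80 (1.62, 0.21) and CD70 higher in all 3 lines, with CD70, the ligand of CD27, at 5.75, 0.07 and 1.23 in U266, RPMI-8226 and ARP-1. Death receptor and apoptosis genes (0.137) had BCL2A1 (2.46, 0.21) and TNFSF10 (0.68, 0.14), which encodes TRAIL, higher in all 3 lines and CD59 (-0.89, -0.13), an inhibitor of complement, lower. Adhesion genes (0.583) had ITGB1 (-2.00, -0.62), CDH2 (-1.43, -0.34) and ITGA6 (-1.32, -0.88) lower in all 3 lines and ITGB2 (1.57, 0.12) higher. That list was tested as lower although its median change was 0.02 and its mean change -0.02. The S100 list (0.946, 8 genes, including S100PBP, which encodes a binding protein of S100P and not an S100 protein) had S100A11 (-2.21, -0.63) and S100PBP (-0.17, -0.08) lower in all 3 lines and S100A4 (0.55, 0.60) and S100A2 (0.42, 0.44) higher. Translocation and cyclin D genes (0.188) had FGFR3 (-2.93, -0.16) and MAF (-1.13, -1.08) lower in all 3 lines and CCND2 (2.43, 0.13) and MAP3K14 (0.66, 0.15) higher. FGFR3 lay below the filter value with both vectors in RPMI-8226 and ARP-1, so its direction there carries no weight. MAF, ITGB1 and S100A11 are among the 85 genes at least 32-fold higher in ARP-1, and MAF differed by -1.98 in RPMI-8226 and -0.17 in ARP-1. For most of these genes the mean with 3 pairs rests on the array labelled U266 CD85j.

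In the ARP-1 pair, the gain of HLA-DRA with CD85j came to 6.82% of its RPMI-8226 signal, that of HLA-DPA1 to 0.953%, that of HLA-F to 6.10%, that of HLA-B to 36.4% and that of NLRC5 to 54.4%. Of 42 genes at least 32-fold higher in the RPMI-8226 arrays and the array labelled U266 CD85j than in the U266 GFP and ARP-1 GFP arrays, 29 were higher in ARP-1 CD85j, with a median gain of 0.169% of the RPMI-8226 signal (quartiles -0.0574% and 0.308%). The mean log2 value of the poly-A spike probe sets was 8.84 in U266 GFP, 6.71 in the array labelled U266 CD85j, 7.84 and 6.88 in the RPMI-8226 GFP and CD85j arrays, and 6.77 and 7.79 in the ARP-1 GFP and CD85j arrays.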
